A study of Homo sapiens with 6 samples.

How the data were processed

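ChIRP-seq of the DINO RNA was done in doxorubicin-treated U2OS cells. Per the labels' protocols, cells were crosslinked with glutaraldehyde, the chromatin was fragmented, and sequencing libraries were made with a kit for ChIP-seq. Per the series' design text, even and odd probe sets were used on untreated and RNase-treated chromatin. Of the 6 samples, 4 had a peak list (even and odd probe sets, each without and with RNase), and the untreated and RNase-treated input samples were not used here. There was 1 library per condition, so no replicate spread could be measured and no test between libraries was run.

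The submitters' processing notes name Bowtie, MACS2 and the genome build hg19. Their versions, the threshold and the control library of the peak calls are not given in the sources used here. The name of each peak carries its library, so the authors called peaks for each library on its own. The deposited lists have the narrowPeak layout without a header, and the columns were read by that layout. The score of each peak in the deposited lists is 10 times its −log10 q-value, less any decimals, in all but 1 peak. The fold enrichment of each peak is a linear ratio over the background modelled by the peak caller, as the authors deposited it. The −log10 p-value and −log10 q-value at the summit are also the authors' values, and the lowest −log10 q-value in the 4 deposited lists is 2.01. The last peaks of mitochondrial DNA end at 16571 in all 4 lists. Read numbers were not used here, and a library that was sequenced more deeply or enriched against another control can give more peaks, so numbers of peaks were not read as amounts of recovered DNA.

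Peaks on chromosomes 1 to 22 and X were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Coordinates are 1-based and in hg19. Peaks overlapped when they shared at least 1 bp. For pairs of lists, the 34695 strongest peaks of each list by −log10 p-value were used, the length of the shortest list, and shares have Wilson 95% intervals, which cover counting error only. Each observed overlap was set beside 1000 circular shifts of a list, by at least 1000000 bp along each chromosome, which keep the spacing and widths of peaks. A region found by both probe sets is the union of overlapping even and odd peaks, with the highest fold of each set. It was called RNase-sensitive when none of its peaks overlapped a peak of either RNase-treated list, and the reverse count was made in the same way. For these counts the untreated and RNase-treated odd lists were shifted together. Density is the number of peaks divided by the position of the last peak end on the chromosome. The counting was tested on simulated lists of 25750 even and 11250 odd peaks, in which all of 750 planted untreated regions of both probe sets and all of 150 planted RNase-sensitive regions were recovered. Planted positions were kept apart from each other, so this checked the counting only and not overlaps that arise by chance.

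The comparisons, the alternatives and the rule for named positions were fixed before the data were examined. The rule names the CDKN1A and DINO locus, the 15 RNase-sensitive regions with the highest smaller fold of both probe sets, the highest-fold peak of each list, and the 5 regions found only after RNase with the highest smaller fold. Without an hg19 annotation, the locus was not found by its gene position. It was taken as the untreated region of both probe sets with the highest smaller fold, so its first rank by that fold follows from this choice. The strongest untreated and RNase-treated regions of both probe sets were named after their values were seen. Alternatives were a q-value threshold, a fold of at least 5, reciprocal 50% overlap, summits within 200 bp, intervals counted once, all sequences, all peaks, ranking by fold, equal numbers of peaks, other definitions of RNase sensitivity, and a wider window at the locus. A −log10 q-value of at least 10 and shifts of 20 to 200 kb were added after the data were seen.

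Planned comparisons with gene lists, of promoters, exons and introns, and of p53 motifs were not run, since no hg19 annotation or sequence was used here. The gene table used here is of the assembly GRCh38.p14, and it served only for the names, lengths and neighbourhood of CDKN1A and DINOL. Positions are therefore given without genes, except at the DINO locus.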

Results

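DINO is a long noncoding RNA that is induced by DNA damage and acts in the p53 response. Its contacts with chromatin were mapped by ChIRP-seq, in which biotinylated oligonucleotides complementary to an RNA pull down crosslinked chromatin and the recovered DNA is sequenced. The cells were U2OS, a human osteosarcoma line with wild-type p53, treated with 0.2 µg/mL of the DNA-damaging drug doxorubicin for 24 h. The probes were divided into 2 independent sets, called even and odd, and each set was used on untreated chromatin and on chromatin treated with RNase, the control for recovery that does not need RNA. Of the 6 samples, 4 had a peak list, 1 for each probe set and RNase state. The 2 input samples were not analysed here. With 1 library per condition there was no spread between replicates, so no p-value between libraries is given. Each difference below compares these libraries. The number of reads behind each list is unknown.

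The first comparison was of the number of peaks in each list and the length they covered. Over all sequences, the untreated even library had 105683 peaks and the untreated odd library 34712. The RNase-treated libraries did not have fewer peaks, with 116185 for the even set, 1.10 times the untreated number, and 57485 for the odd set, 1.66 times. On chromosomes 1 to 22 and X, the intervals covered 24.0 Mb in the untreated even library and 7.47 Mb in the untreated odd library. After RNase they covered 27.6 Mb and 12.6 Mb. Most peaks were narrow, with median widths between 171 bp (untreated odd) and 192 bp (RNase-treated even). The median fold enrichment at the summit was 10.9 in the untreated even list, 10.2 in the untreated odd list, 11.8 in the RNase-treated even list and 10.96 in the RNase-treated odd list. These folds are the authors' own values, made within each list, and serve here mainly to describe and rank its peaks. An alternative definition of RNase sensitivity also compared them between lists.

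The second question was what was recovered at the locus of DINO itself. Probes complementary to this RNA also match the DNA of its gene. Recovery here, above all after RNase, therefore does not by itself show a pull-down of RNA. Of the regions found by both probe sets, the one with the highest smaller fold lay on chromosome 6 at 36644595 to 36646433 (hg19). It was the strongest peak of the untreated odd list, with a fold enrichment of 186, and ranked 5 by p-value in the untreated even list, with a fold of 121. It was also present after RNase, at 36645295 to 36646440, where it ranked 1 in the odd list (fold 300.1) and 4 in the even list (fold 191). From general knowledge of hg19, and not from a file used here, this interval lies at the 5′ end of CDKN1A, which encodes the cell cycle inhibitor p21 and is a p53 target. In the gene table used here, of another assembly, DINO (listed as DINOL, 951 bp long) overlaps CDKN1A. The summits of the untreated and RNase-treated peaks were 26 bp apart in the even set and 37 bp apart in the odd set. High folds were more frequent throughout the RNase-treated lists. A fold of at least 100 was reached by 2129 even and 2167 odd peaks there, against 151 and 311 untreated. The higher folds of this region after RNase therefore do not show more recovery.

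The extent of the locus differed between the RNase states on the side of lower coordinates. The untreated interval began 399 bp before the RNase-treated interval in the even set and 700 bp before it in the odd set, whereas the other ends lay within 21 bp and 7 bp of each other. The interval was 1465 bp wide without RNase and 1087 bp with RNase in the even set, and 1839 bp and 1146 bp in the odd set. Beyond it, both untreated lists held further peaks on the same side that had no counterpart after RNase. In the even list this was a peak at 36644138 to 36644502 with a fold of 33.1. In the odd list these were peaks at 36644005 to 36644174 (fold 7.40) and 36644235 to 36644551 (fold 8.64). On the opposite side, the even peak at 36646528 to 36646752 (fold 13.2) was found again after RNase (fold 12.9), whereas the odd peak at 36646633 to 36646771 (fold 5.88) was not. The even lists shared a further peak at 36650765 to 36650918 (fold 8.25 without RNase and 6.74 with RNase).

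**Figure D1:**
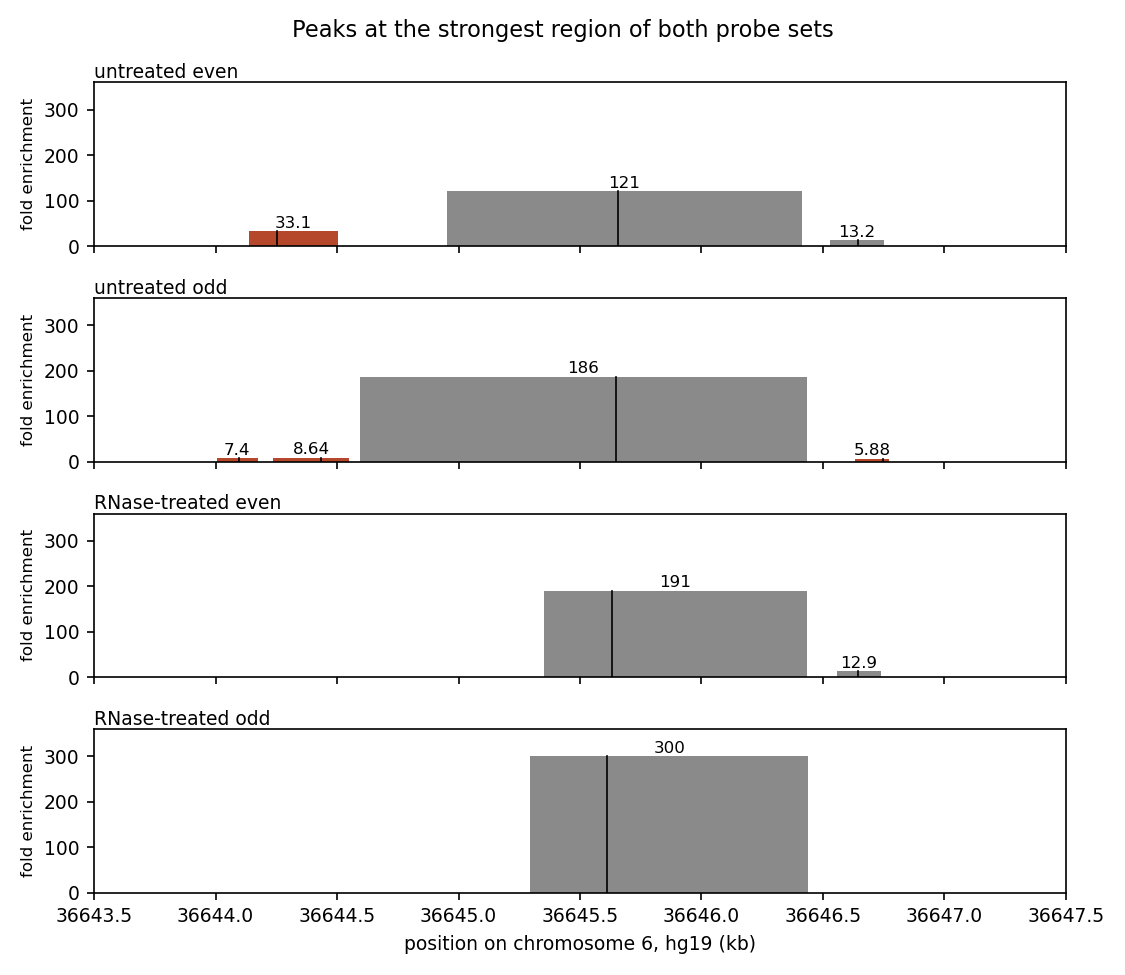
Peaks of the 4 lists at the chromosome 6 region. The horizontal axis is the position on chromosome 6 (hg19, in kb) and the vertical axis the authors' fold enrichment within each list. Bars span the peak intervals, black lines mark the summits, and red bars are untreated peaks without an RNase-treated peak of the same probe set. The central interval is in all 4 lists, with folds of 121, 186, 191 and 300.1, and the red bars at lower coordinates have folds of 33.1, 7.40 and 8.64.

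The third question was whether recovery needed RNA and whether it was shared by the probe sets. The positions of the strongest peaks were shared within a probe set, with and without RNase, far more often than between probe sets. Among the 34695 strongest peaks of each list, 80.1% of the untreated even peaks overlapped an RNase-treated even peak (Wilson 95% interval 79.6 to 80.5), and 80.4% of the untreated odd peaks overlapped an RNase-treated odd peak (80.0 to 80.8). Between the probe sets, 2.06% of the untreated even peaks overlapped an untreated odd peak (1.91 to 2.21), and the share was 1.49% for the RNase-treated lists (1.37 to 1.62). Circular shifts of a list along the chromosomes gave mean overlaps of 0.849% and 0.563% for the same-probe-set pairs, 0.657% for the untreated lists and 0.743% for the RNase-treated lists. The overlap between probe sets was thus 3.13 times the shifted mean without RNase and 2.01 times with RNase. Shifts of 20 to 200 kb gave 0.805% and 0.894% for these lists. The untreated even and RNase-treated odd lists overlapped by 1.42%, which was 1.98 times the shifted mean. The untreated odd and RNase-treated even lists overlapped by 2.15%, which was 3.13 times. The multiple thus went with the odd list used and not with the RNase state of the even list. The equal number kept the whole untreated odd list but only the strongest 34695 of 57466 RNase-treated odd peaks. These multiples therefore do not show more sharing without RNase. With reciprocal 50% overlap the 4 pairs between probe sets fell to 0.432% (untreated), 0.585% (RNase-treated), 0.565% and 0.441%. Over all peaks, 4.04% of the untreated odd peaks overlapped an RNase-treated even peak, against 1.19% in reverse. Summits of overlapping peaks lay a median of 16 bp apart in the even lists and 18 bp apart in the odd lists, against 63 bp for untreated even and odd peaks. The intervals cover counting error only and treat peaks as independent, which neighbouring peaks are not.

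The strongest peaks were kept most often after RNase. Over all peaks, 80.9% of the untreated even list and 91.6% of the untreated odd list overlapped a peak of the same probe set after RNase. In reverse, 73.5% of the RNase-treated even peaks and 55.2% of the RNase-treated odd peaks overlapped an untreated peak of the same set, which left 30816 and 25729 peaks found only after RNase in that set. In the strongest 10% of each untreated list, ranked by p-value, these shares were 99.7% (10538 of 10567 peaks) and 100% (3470 of 3470 peaks). In the weakest 10% they were 53.4% and 69.2%. The 20207 even peaks without an RNase-treated counterpart had a median fold of 7.14, and the 85462 with one had a median fold of 12.7. In the odd list the values were 6.06 for 2918 peaks without and 11.1 for 31777 peaks with a counterpart.

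**Figure D2:**
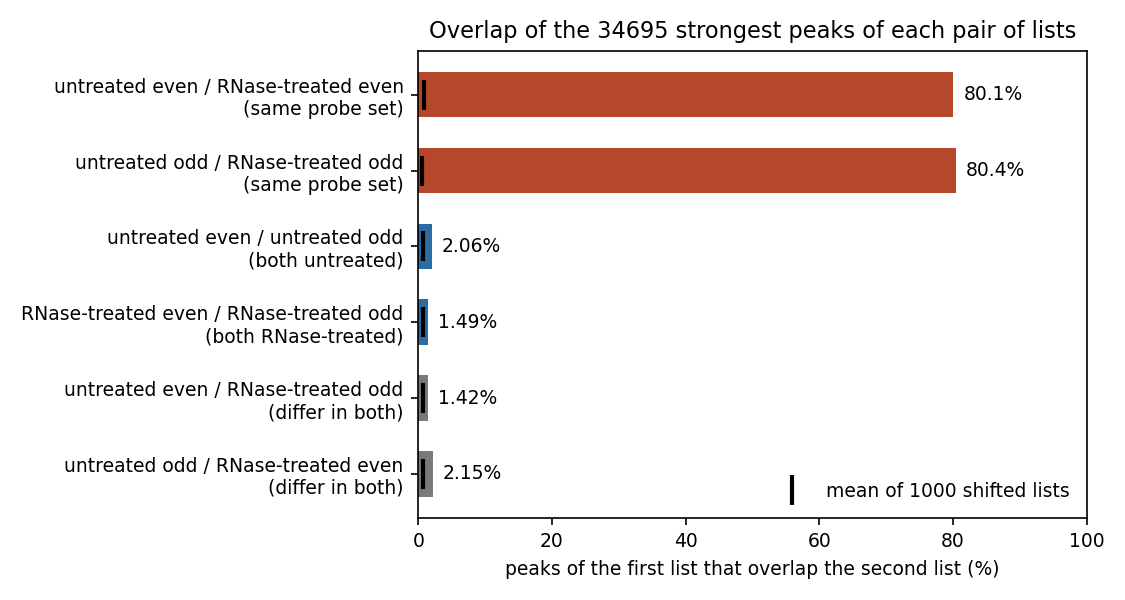
Overlap of the 34695 strongest peaks between each pair of lists. The horizontal axis is the percentage of peaks of the first list that overlap the second by at least 1 bp, bars are observed values, and black marks are means of 1000 circular shifts. Lists of the same probe set share 80.1% and 80.4% of their peaks, and the other 4 pairs share between 1.42% and 2.15%.

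Regions found by both probe sets were then examined, since a contact of the RNA should be seen by each set. The untreated lists had 1292 such regions, against a mean of 546 in 1000 shifts (highest 651). The RNase-treated lists had 1866, against a mean of 1015 (highest 1118). Shifts of 20 to 200 kb, which keep the neighbourhood, gave higher means of 655 and 1175. The order of these counts followed the lengths of the lists, because with the same number of top peaks in every list there were 712 regions without RNase and 516 with RNase. Besides the chromosome 6 region, none of the 1292 untreated regions had a fold of at least 100 in both sets, and 8 regions including it had a fold of at least 50 in both. The next were on chromosome 22 at 47399078 to 47402149 (even 85.3, odd 58.8) and on chromosome 21 at 45023553 to 45025981 (even 56.4, odd 97.3). The chromosome 22 region was also second among the RNase-treated regions, at 47399035 to 47402159 (even 115, odd 114). The third RNase-treated region lay on chromosome 7 at 11179488 to 11180114 (even 107, odd 145).

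**Figure D3:**
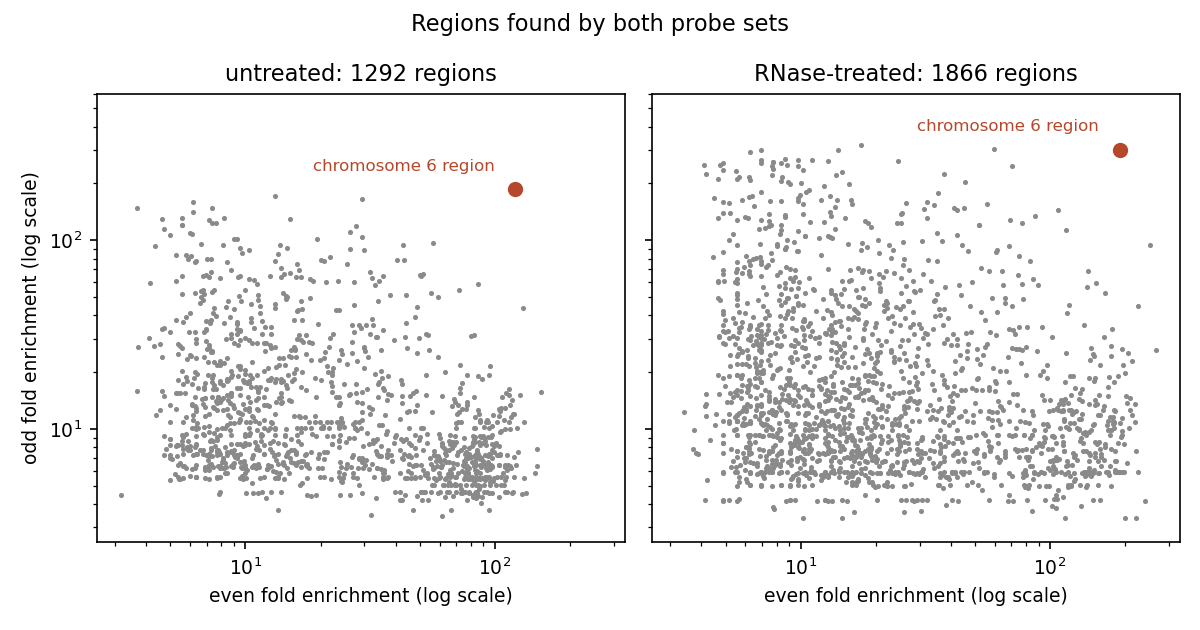
Fold enrichment of the regions found by both probe sets, without RNase (left, 1292 regions) and with RNase (right, 1866 regions). Each point is a region, the horizontal axis is its even fold and the vertical axis its odd fold, both on a log scale. The chromosome 6 region, in red, has the highest smaller fold in both panels, with 121 on the left and 191 on the right.

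Of the 1292 untreated regions found by both probe sets, 15 overlapped no RNase-treated peak of either set, which is 1.16%. Shifted lists gave a mean of 5.82 such regions, between 0 and 15, and 1 of the 1000 shifts gave as many. Such regions made up 1.07% of the shifted regions. With shifts of 20 to 200 kb the mean was 7.25 and 10 of 1000 gave as many. The reverse count, regions found by both RNase-treated lists that overlapped no untreated peak, was 111 of 1866 (5.95%), against a mean of 80.7 (7.95% of the shifted regions), and 2 of the 1000 shifts gave as many. With equal numbers of peaks in every list the counts were 20 (shifted mean 6.54) and 13 in reverse (shifted mean 7.37). Only 2 of the 15 regions were among the 20. The other regions of the 15 dropped out because the untreated even list was cut from 105669 to 34695 peaks, which removed their even peaks. Shortening the RNase-treated lists can only add regions to the 20, by removing peaks that regions would otherwise overlap. The rest of the 20 arose in this way, since over all peaks they belonged to regions that overlapped an RNase-treated peak. They are thus not RNase-sensitive over the full lists. The reverse count of 13 is open to the same effect of shortened lists. With a −log10 q-value of at least 10, a threshold chosen after the data were seen, 3 RNase-sensitive regions were left, and 277 of the 1000 shifts gave as many. The reverse count was then 78, against a shifted mean of 44.4, and 0 of the 1000 shifts gave as many.

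The 15 RNase-sensitive regions lay on 9 chromosomes and were 164 to 547 bp wide, and the smaller of the even and odd folds ranged from 4.49 to 9.01. The first by this smaller fold was on chromosome 19 at 56110210 to 56110380 (even 9.01, odd 10.7). The second was the flank of the chromosome 6 locus at 36644005 to 36644551 (even 33.1, odd 8.64), 743 bp from the nearest RNase-treated peak, and no other of the 15 lay within 1 kb of such a peak. The third was on chromosome 11 at 386446 to 386640 (even 8.75, odd 7.54), and the next on chromosome 3 at 131088626 to 131088951 (even 7.11, odd 7.16). In order of the smaller fold, the others lay on chromosome 1 at 87705442 to 87705620, chromosome 19 at 40972535 to 40972796, chromosome 2 at 56150686 to 56150891, chromosome 11 at 65777743 to 65777969 and chromosome 22 at 19348063 to 19348278. They were followed by chromosome 1 at 36034735 to 36034914, chromosome 15 at 64086606 to 64086835, chromosome 2 at 76057403 to 76057697, chromosome 11 at 22031064 to 22031312 and 132273853 to 132274016, and chromosome 12 at 117993608 to 117993858. The last had folds of 17.6 in the even list and 4.49 in the odd list. The genes at these positions were not analysed here.

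The 5 strongest regions found only after RNase had smaller folds between 9.32 and 15.3. They lay on chromosome 15 at 88972781 to 88973231 (even 15.3, odd 16.1), chromosome 8 at 66862637 to 66862981 (even 11.1, odd 13.0), chromosome 3 at 186926788 to 186926958 (even 11.5, odd 9.997), chromosome 12 at 24849452 to 24849746 (even 9.52, odd 14.04) and chromosome 16 at 28512078 to 28512318 (even 10.2, odd 9.32). The nearest untreated peak lay 44, 332, 8085, 357 and 152 bp away in this order, and 11 of the 111 regions lay within 1 kb of such a peak.

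The peak with the highest fold was a different position in each list. In the untreated even list it was on chromosome 13 at 109945459 to 109947313, with a fold of 153. Peaks of the other lists at this position had folds of 15.7 (untreated odd), 265 (RNase-treated even) and 26.2 (RNase-treated odd). In the untreated odd list it was the chromosome 6 region. In the RNase-treated even list it was on chromosome 4 at 180584678 to 180585732 (fold 293), where the untreated even list had a fold of 143 and neither odd list had a peak. In the RNase-treated odd list it was on chromosome 15 at 57256430 to 57257115 (fold 318), where the folds were 159 in the untreated odd list, 6.15 in the untreated even list and 17.5 in the RNase-treated even list.

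Peaks were spread over all chromosomes in each list. The X chromosome had the lowest density, with 16.5 peaks per Mb in the untreated even list, 5.95 in the untreated odd list, 21.6 in the RNase-treated even list and 11.4 in the RNase-treated odd list. Chromosome 20 had 47.9, 14.6, 50.5 and 22.5 peaks per Mb in the same order. Across the 23 chromosomes, which are not replicates, the densities of the untreated and RNase-treated lists correlated with a Pearson r of 0.98 in each probe set. The r was 0.88 for the untreated even and odd lists and 0.87 for the RNase-treated lists (Spearman rho 0.75 and 0.73). It was 0.93 for the untreated odd and RNase-treated even lists and 0.79 for the untreated even and RNase-treated odd lists. The DNA copy number of U2OS, an aneuploid line, was not analysed here.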

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

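Mitochondrial DNA was left out of the comparisons of peak positions, and more of it was covered by peaks without RNase than with RNase in both probe sets. Untreated even peaks covered 3449 of its 16571 bp (20.8%), against 2107 bp (12.7%) in the RNase-treated even list. Untreated odd peaks covered 4801 bp (29.0%), against 2129 bp (12.8%) in the RNase-treated odd list. The highest folds there were 4.79 and 9.43 without RNase and 3.20 and 3.92 with RNase, each within its own list. Chromosome Y, also left out of the comparisons, went the other way. Its peaks covered 682 bp without RNase against 941 bp with RNase in the even set, and 502 bp against 1891 bp in the odd set. Only a sequence covered more without RNase was flagged.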

How the results depend on the processing

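A −log10 q-value of at least 2 and counting intervals once removed no peak, so they tested nothing. Of the 84 values recomputed under other alternatives, 47 stayed within their 95% interval or within 1.5 times of the reported count, and 37 moved further. The same-probe-set overlaps stayed far above the others in each setting run. They were 79.5% (even) and 74.8% (odd) with reciprocal overlap, 80.9% and 91.6% over all peaks, 78.1% for even peaks ranked by fold and 83.1% for odd peaks with a −log10 q-value of at least 10. The untreated even and odd overlap was 1.89% with a fold of at least 5, 0.432% with reciprocal overlap, 1.74% by summits and 1.27% with a −log10 q-value of at least 10. Over all peaks it was 1.23% of the untreated even peaks and 3.78% of the untreated odd peaks. For the RNase-treated lists it was 0.585% with reciprocal overlap, 1.06% by summits and 1.06% with a −log10 q-value of at least 10. Regions of both probe sets numbered 356 without and 613 with RNase under reciprocal overlap, and 618 and 1083 with a −log10 q-value of at least 10. With equal numbers of peaks they numbered 712 and 516, where fewer peaks were used by construction in every list but the untreated odd one. RNase-sensitive regions fell to 3 with a −log10 q-value of at least 10, and ranged from 13 to 22 in the other settings. Of the 15 regions, 9 were kept with reciprocal overlap, 2 with a −log10 q-value of at least 10 and 2 with equal numbers of peaks, although 20 regions were then counted. The chromosome 6 flank was kept in each setting but the absence of RNase-treated peaks within 1 kb. Regions found only after RNase numbered 57 with reciprocal overlap and 13 with equal numbers. They numbered 365 when an untreated peak of the same set was allowed at up to 50% of the fold. That setting compares folds between lists and does not check the other probe set. A −log10 q-value of at least 10 left 37780 RNase-treated odd peaks. Within 50 kb of the locus, 2 even peaks had no counterpart after RNase, against 1 within 5 kb. The correlations over chromosomes rose to 0.996 (even) and 0.995 (odd) with equal numbers. Apart from settings that use fewer peaks, the cause was not tested. The comparisons that need a gene annotation or the genome sequence, and their alternatives, were not run. With the number of reads unknown, what depth limits cannot be given, and the loss of a weak peak is not evidence of loss of signal.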

Other observations

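The tests in this part were chosen after the results they bear on were seen, except that of interval width at the chromosome 6 region.

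Peaks were shared far more often within a probe set than between probe sets. Unequal list lengths are argued against, since with equal numbers the smallest same-set overlap exceeded the largest other overlap by 77.9 percentage points. DINO RNA left on the chromatin by incomplete digestion should be recovered by both sets, but at most 2.64% of the positions kept after RNase in a set were in both lists of the other set. That share was bound to be small, since only 3.78% of all untreated odd peaks overlapped an untreated even peak. It restates the pattern and is not separate evidence on digestion. Capture of DNA by each oligonucleotide pool without RNA stays open and was not tested apart from the pattern itself, since probe sequences were not used here. An RNA contact at a minority of positions stays open too.

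Of the 1000 strongest untreated even peaks, 24.3% overlapped an untreated odd peak, against 1.01% of the rest. The RNase-treated even list showed this too (17.9% against 1.47%), and the odd lists less so, with 5.7% against 3.72% without RNase (highest shift 4.3%) and 8.8% against 3.18% with RNase, and in the untreated odd list the weakest 10% also reached 5.59%. For the untreated even peaks, the greater width of strong peaks is argued against, since shifts gave at most 1.8%. Sites strongly enriched in both untreated lists are argued against, since the odd partners had a median percentile of 24.4 in their own list. Sites recovered in every pull-down at unlike strength stay open. Of all 1298 untreated even peaks with an untreated odd partner, 854 overlapped a peak of each of the other lists. Reads passing between libraries cannot be told apart from weak capture of the same DNA by the other pool, since both place summits together, as in 61.3% of the pairs within 50 bp. The folds of the partners did not follow those of the even peaks (Spearman rho 0.02 over 253 pairs), which decides little because partners below the calling threshold are missing from the list.

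At the chromosome 6 region, the side of lower coordinates was called only without RNase, in both probe sets. Untreated intervals wider in general by as many bp are argued against. At most 0.4% of the 1000 strongest RNase-treated peaks of a set, this region included, had an untreated interval reaching as far beyond them. These peaks had mean widths of 617 bp (even) and 551 bp (odd), against 1087 bp and 1146 bp for the RNase-treated intervals here. Widening in proportion to the width of a peak was therefore not tested and stays open. Chance loss is argued against for the even flank peak, since 0.5% of the 1000 peaks nearest to it in rank had no RNase-treated counterpart, but it remains possible for the odd flank peaks, where the share was 7.6% for the stronger and 16.4% for the weaker. Suppression of flank calls beside very strong RNase-treated peaks cannot be told apart, since with this region left out 16.7% of only 24 such even peaks were lost (Wilson 95% interval 6.68 to 35.9), against 19.1% of the whole list. RNA-dependent recovery beside the DINO locus, which the RNase control was designed to show, may also account for this flank and stays a hypothesis that rests on 1 library per condition.

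The hypothesis that RNA-dependent recovery spreads in cis from the locus was tested within 5 Mb of it, leaving out 10 kb on both sides. Of the untreated even peaks there, 23.1% (134 of 580) had no RNase-treated even counterpart, at percentile 94.0 of 961 windows elsewhere. Of the untreated odd peaks, 7.41% (12 of 162) had none, at percentile 38.9 of 923 windows. The higher percentile was below 95 and the probe sets differed, so the data gave no support for such spreading at this scale.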
